A study of Homo sapiens with 4 samples.

How the data were processed

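Gene expression was measured in MCF7 cells, an estrogen receptor-positive human breast cancer line, after lentiviral delivery of an shRNA. The shRNA was either a non-specific control or one against PDEF, an ETS-family transcription factor whose gene symbol is SPDEF. All cultures were kept in hormone-depleted medium for 48 hours. Each group had 2 arrays, which the labels call biological replicates, so the data comprised 4 arrays.

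Per the labels' protocols, total RNA was prepared with Trizol and purified on RNeasy columns. It was primed with a T7-tailed oligo-dT primer, amplified by in vitro transcription and labelled with biotin. This labelling starts at the poly(A) tail, so the probe sets read the 3′ part of transcripts. The submitters' processing notes name RMA and limma, with no versions. The deposited values were on the log2 scale and their distributions were nearly the same in all arrays, as quantile normalization in RMA gives. RMA summarises several probes into 1 value per probe set, and its quantile step removes any difference that would shift most genes the same way. RMA values of dim probe sets are compressed, so fold changes of weakly expressed genes are understated. The scanner images and probe-level intensities were not used here. The genome build was not given in the sources used here, and no coordinates are reported.

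The table held 54675 probe sets. Gene symbols came from the array's platform annotation: 41097 probe sets had 1 symbol, 1801 had several and 11777 had none listed. Of those with 1 symbol, 41043 were matched by gene ID to the RefSeq gene table of GRCh38.p14, and 0 symbols changed. Probe sets with several symbols or none named no gene. For each of 19775 genes the probe set with the highest mean over the 4 arrays represented the gene, and disagreement between a gene's probe sets is given where it changes a call. Probe sets whose IDs end in _x_at may also detect related transcripts. No filter on dim probe sets was applied. The number of arrays limits the precision of every value.

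PDEF shRNA was compared with control shRNA in R 4.3.3 with limma 3.58.1 (lmFit and eBayes, default prior, no covariate). Every log2 fold change is PDEF shRNA minus control shRNA, with the standard error (SE) from limma. P-values were two-sided and adjusted by the Benjamini-Hochberg method over all genes, with a threshold of 0.05. The fit had 2 residual degrees of freedom and a prior of 3.63, and 5 genes had a residual variance of 0. The words rose and fell are used only for genes past this threshold. Group values are means ± SD of log2 values.

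Before the data were examined, 21 gene lists, the test, the alternatives and the rule for named genes were fixed. The lists came from general knowledge of mammary epithelium, PDEF, hormone depletion, lentiviral shRNA and cell stress, and 3 of them hold markers of other cell types. Each list was tested with camera in limma at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 21 lists. Camera with an estimated correlation and fry were alternatives. Members were counted over all genes tested and adjusted over the list alone. A further 6 lists were chosen after seeing the data and adjusted among themselves.

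The genes named were SPDEF, then ESR1, GATA3, FOXA1, PGR, TFF1, BCL2, CEACAM6, AGR2, CDKN1A and MKI67 whatever their values. Added to these were the 15 genes that rose and the 15 that fell with the largest absolute log2 fold change among those whose values did not overlap between groups. If fewer than 5 had passed in a direction, the 10 with the smallest p would have been named. For each list, up to 4 members past the threshold with the largest absolute log2 fold change were named, or the 2 largest, as values, where none passed. Any other gene named was chosen after its values were seen.

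The alternatives were another quantile normalization, cyclic loess, centring on array medians, 2 filters on dim genes (a mean of at least 5, and the brighter 9888 genes by mean), the mean of a gene's probe sets, every probe set tested, a trended and robust prior, array weights, the replicate number as a block, other thresholds, and each array left out in turn. Leaving out an array leaves 1 array in its group, which is then assumed to vary like the other group. Counts per list under these settings, the contrast between replicate numbers and the 6 further lists were added after seeing the data. Signs of array quality were read from 18 bacterial hybridisation control probe sets, from the 3′ minus 5′ difference of the GAPDH and ACTB control probe sets, and from 3 HUMRGE control probe sets.

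The gene test was tested on simulated data for 19775 genes, 200 of them changed. It recovered 80 of 100 genes changed by 1 on the log2 scale and 98 of 100 changed by 2, and 17 of its 198 calls were genes simulated without change. Another 3 calls were members of the shifted list. A simulated list of 30 genes shifted by 0.5 gave a camera p of 2.33e-37, and an unshifted list gave 0.699. Noise was drawn independently for each gene from limma's fitted variance prior. The simulation therefore does not test camera on lists whose members are correlated. To set a list's median against chance, 10000 random lists of the same size were drawn, matched on mean expression within 100 ranks on each side. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.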

Results

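The data were 4 microarrays of MCF7 cells, 2 with control shRNA and 2 with PDEF shRNA, all hormone-depleted for 48 hours. Each array gave log2 values for 54675 probe sets, with medians of 6.16, 6.18, 6.16 and 6.17 in control replicates 1 and 2 and PDEF shRNA replicates 1 and 2. Pearson's r across probe sets, which are not independent replicates, was 0.994 between the control arrays and 0.996 between the PDEF shRNA arrays. Between groups it ran from 0.991 to 0.992. Hybridisation control probe sets had medians of 11 and 10.6 in the control arrays and 10.4 and 10.8 in the PDEF shRNA arrays. The 3′ minus 5′ difference of GAPDH was 0.43 and 0.33 in the controls and 0.27 and 0.41 with PDEF shRNA, and that of ACTB was 0.53, 0.41, 0.28 and 0.41 in the same order. The HUMRGE control probe sets averaged 8.59 in control replicate 1, against 7.10, 6.97 and 7.56 in the other arrays.

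The comparison asked which transcripts change when PDEF is depleted in luminal breast cancer cells. No array has loss of PDEF without the hairpin, or the reverse. For every gene and list below, an effect of the hairpin or vector therefore cannot be told apart from loss of PDEF. SPDEF itself was 10.31 ± 0.21 in the control arrays and 7.69 ± 0.36 in the PDEF shRNA arrays (SD, n = 2). It was 6.14-fold lower, at 16.3% of the control level (log2 fold change −2.62 ± 0.20 SE, limma adjusted p = 0.0069). All 5 SPDEF probe sets were lower in both PDEF shRNA arrays than in both controls, and 3 passed when every probe set was tested. The other 2 that passed were 2.66-fold and 2.04-fold lower, and those that did not pass differed by −0.08 and −0.07. All SPDEF probe sets are of the kind that may also detect related transcripts. With 1 array left out the call ended: adjusted p was 0.062 and 0.072 without control replicate 1 or 2, and 0.098 and 0.067 without PDEF shRNA replicate 1 or 2. The log2 fold change was then −2.47, −2.77, −2.37 and −2.87.

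Of 19775 genes, 324 changed (1.64%), of which 220 rose and 104 fell. The risers were led by IFIT1, an interferon-induced RNA-binding protein, which was 11.5-fold higher (7.38 ± 0.31 to 10.89 ± 0.03, SD, n = 2). IFI27 (7.47-fold), OAS1 (6.44-fold) and IFIH1 (5.84-fold) followed, then DIO2, a deiodinase that activates thyroid hormone, at 5.76-fold. Among the next were the interferon-induced SAMD9, DDX60, IFI6, HERC6, PARP14 and CMPK2, together with PLS3, PHLDB2, KLHDC7B and SNAI2. After SPDEF, the largest falls were those of MSMB (4.83-fold lower), the secreted mucin MUC5B (4.04-fold), PLCB4, GPC1-AS1, ELAPOR1 and CRISP3. ERBB4, a receptor of the EGFR family, was 3.04-fold lower, CEACAM5 2.82-fold and AGR2, a disulfide isomerase of secretory cells, 2.81-fold. SLC2A10, ALCAM, TSPAN13 (2.63-fold), CSTA and MPPED2 completed the 15. GPC1-AS1 is annotated as an antisense transcript and is uncertain, since its probe set was not checked against the GPC1 strand. A change of at least 1 on the log2 scale was met by 122 of the genes that rose and 34 of those that fell. The count depended on each array: 54 genes without control replicate 1 and 21 without control replicate 2. Without PDEF shRNA replicate 1 or 2, limma gave 0 genes, with 1427 and 1460 at an unadjusted p under 0.05 against 2441 with all arrays.

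**Figure D1:**
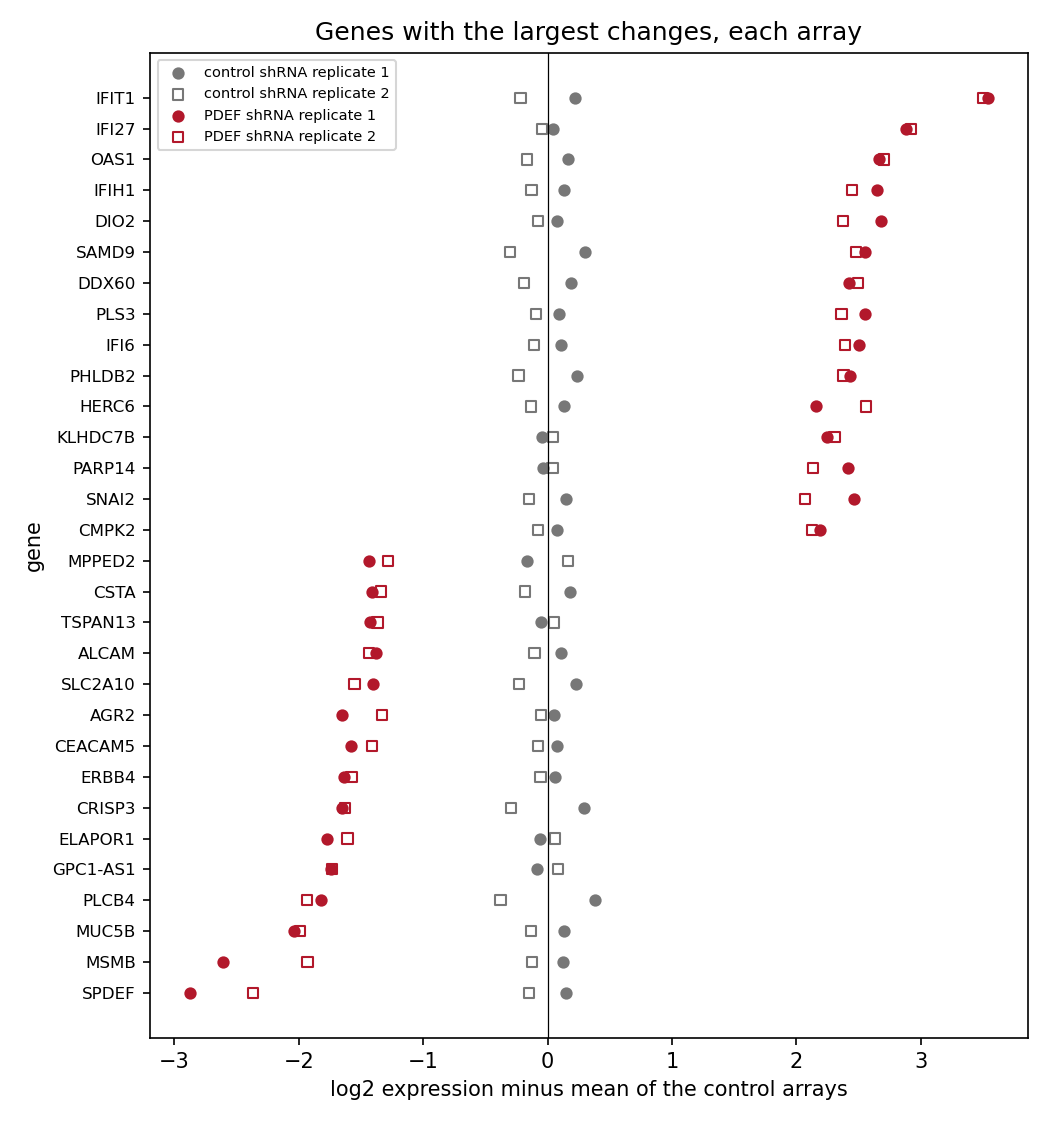
Each row is 1 of the 15 genes that rose or the 15 that fell with the largest change; points are the 4 arrays and the horizontal axis is the log2 value minus the mean of the control arrays. The genes were chosen among those whose values do not overlap between groups, and the mean differences run from −2.62 for SPDEF to 3.52 for IFIT1.

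Genes of the interferon and double-stranded RNA response rose together. Of 36 measured members 26 rose and 0 fell, and 32 rose adjusted over the list alone. All 36 had a positive log2 fold change, with a median of 1.41. The values were 3.52 ± 0.16 for IFIT1, 2.90 ± 0.09 for IFI27, 2.69 ± 0.13 for OAS1, which makes the RNase L activator, and 2.55 ± 0.13 for IFIH1, a sensor of double-stranded RNA (adjusted p 0.0027 to 0.0031, limma). For the list, camera gave an adjusted p of 9.27e-48 at the preset correlation, and adjusted p = 0.129 with an estimated correlation. The list's median was 1.34 between the replicate 1 arrays and 1.46 between the replicate 2 arrays. The number that rose was 14 and 8 without control replicate 1 or 2. It was 0 without PDEF shRNA replicate 1 or 2, where limma gave 31 and 30 members at an unadjusted p under 0.05. The interferon transcripts IFNB1, IFNL1 and IFNA1, chosen after their values were seen, did not pass. Their log2 fold changes were 0.39, 0.47 and 0.03. Other interferon genes are not given, and fold changes of dim probe sets are understated. These values therefore cannot show that no interferon was induced.

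Some secretory and luminal genes fell, and both lists were lower in the test. Of 33 measured goblet and mucus secretory genes 4 fell and 0 rose (10 fell and 1 rose adjusted over the list alone), with a median of −0.19. They were MUC5B at −2.01 ± 0.12, AGR2 at −1.49 ± 0.13, TSPAN13 at −1.40 ± 0.09 and GALNT12, which starts O-glycan chains on mucins, at −0.82 ± 0.12 (adjusted p 0.0039 to 0.043, limma). When every probe set was tested, this GALNT12 probe set did not pass, and the gene's other probe set passed at −1.29. With camera the adjusted p was 1.78e-07, and adjusted p = 0.129 with an estimated correlation. Of 33 luminal and mammary differentiation genes 3 fell and 0 rose, and 7 fell adjusted over the list alone. They were AGR2, the membrane mucin MUC1 (−1.27 ± 0.10, 2.41-fold lower) and ESR1, the estrogen receptor alpha gene (12.18 ± 0.13 to 11.29 ± 0.17, SD, n = 2). ESR1 was 1.85-fold lower (adjusted p = 0.039), but its 9 probe sets ranged from −0.89 to −0.05. It did not pass as the mean of its probe sets (−0.47, adjusted p = 0.176) or when every probe set was tested (adjusted p = 0.059). With fry the luminal list did not pass (adjusted p = 0.111). Its median was −0.09 and its camera adjusted p 0.0025, with adjusted p = 0.168 with an estimated correlation. Without control replicate 2 its adjusted p was 0.053. Positive log2 fold changes were found for 13 of the 33, among them the luminal keratin genes KRT8 (0.11) and KRT18 (0.08), chosen after their values were seen, which did not pass. GATA3 and FOXA1, luminal transcription factors, did not pass at −0.07 ± 0.09 and −0.26 ± 0.10. With an array left out, at most 2 goblet genes fell (without control replicate 1). Another 1 fell without control replicate 2, and 0 fell without either PDEF shRNA array, where limma gave 11 and 10 at an unadjusted p under 0.05. No luminal gene fell in any of these 4 fits, where limma gave 7 to 12 at an unadjusted p under 0.05.

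Some basal and mesenchymal genes rose, and both lists were higher in the test. SNAI2, a transcription factor of basal mammary cells, rose 4.82-fold (6.99 ± 0.21 to 9.26 ± 0.28, SD, n = 2). Of 23 measured basal and myoepithelial genes 4 rose and 0 fell, and 9 rose adjusted over the list alone, with a median of 0.39. The other 3 were S100A2 (2.69-fold), LAMB3, a laminin chain (0.81 ± 0.12), and TAGLN, an actin-binding protein of smooth muscle (0.63 ± 0.09). When every probe set was tested, the only LAMB3 probe set did not pass. Of 3 TAGLN probe sets, which ran from −0.07 to 1.33, 1 passed, but not the one that represents the gene. The camera adjusted p was 1.94e-05, and adjusted p = 0.129 with an estimated correlation. Of 27 epithelial-mesenchymal transition and migration genes 5 rose and 0 fell, with 8 adjusted over the list alone and a median of 0.17. SNAI2, the collagen cross-linking enzyme LOXL2 (4.21-fold), the growth factor TGFB2 (3.94-fold) and TGFBI (2.06-fold) led it, with PLAU. Its camera adjusted p was 8.98e-07, and adjusted p = 0.129 with an estimated correlation. Several defining markers, chosen after their values were seen, did not pass: the basal keratin genes KRT5 and KRT14 were at −0.10 and −0.22, EGFR at −0.83, and the mesenchymal VIM, CDH2 and ZEB1 at 0.13, −0.02 and −0.03. Apart from EGFR, their control means ran from 4.83 to 6.44, around or below the control array medians of 6.16 and 6.18. At such levels fold changes are understated, so a change could be missed. In each of the basal and mesenchymal lists 1 gene rose without control replicate 1. Without any 1 of the other 3 arrays limma gave 0, with 9 to 13 basal and 8 to 10 mesenchymal genes at an unadjusted p under 0.05. Among 22 genes reported in relation to PDEF, 3 rose and 3 fell, with 6 and 7 adjusted over the list alone. SNAI2, SERPINB5 (0.93) and PLAU (0.70) rose, and CEACAM5, AGR2 and CEACAM6 (2.09-fold lower, adjusted p = 0.031) fell. The list did not pass (median −0.03, camera adjusted p = 0.398), and 14 of its genes are also in another list. Camera tests for a shift in 1 direction, so it cannot show whether a list with changes in both directions responded as a set. Fry for changes in either direction gave an unadjusted p of 0.00305. That test does not compare a list with other genes. The cholesterol and fatty acid synthesis list, where limma called 0 genes, gave 0.00242 with it, so it does not set this list apart. With limma 13 of the 22 had an unadjusted p under 0.05, against 2441 of all 19775 genes. With any 1 of the 4 arrays left out limma gave 0 of its genes, with 11 to 13 at an unadjusted p under 0.05.

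Cell cycle genes were lower. All 42 measured members had a negative log2 fold change, with a median of −0.59. Of these 12 fell and 0 rose, and 42 fell adjusted over the list alone. The mitotic kinesin KIF11 fell by 0.93 ± 0.13, cyclin A gene CCNA2 by 0.84 ± 0.10, CDK1 by 0.83 ± 0.09 and the ribonucleotide reductase subunit RRM2 by 0.81 ± 0.09 on the log2 scale (adjusted p 0.017 to 0.039, limma). KIF11 did not pass when every probe set was tested. MKI67, the gene of the Ki-67 proliferation antigen, was at −0.63 ± 0.10 with an adjusted p of 0.056 (limma). Its 4 probe sets ran from −0.85 to −0.63, and 1 passed when every probe set was tested. With camera the adjusted p was 1.91e-39, and adjusted p = 0.129 with an estimated correlation. All 42 genes were lower with PDEF shRNA between the replicate 1 arrays and between the replicate 2 arrays, with medians of −0.71 and −0.46. With any 1 of the 4 arrays left out, 0 members fell, while limma gave 36 to 40 at an unadjusted p under 0.05.

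Genes of the p53 target list rose in part. Of 22 measured 4 rose and 0 fell, and 11 rose adjusted over the list alone, with a median of 0.35. They were the stress gene GADD45A (4.19-fold), TIGAR (1.05 ± 0.13), and the death receptor genes FAS (0.99 ± 0.14) and TNFRSF10B (0.74 ± 0.11). When every probe set was tested, 0 of 4 TNFRSF10B probe sets passed, and 2 of 5 FAS probe sets passed, but not the one that represents the gene. The cyclin-dependent kinase inhibitor gene CDKN1A was at 0.83 ± 0.18 with an adjusted p of 0.119. The list's camera adjusted p was 6.07e-09, and adjusted p = 0.129 with an estimated correlation. Without control replicate 1 or 2 the number that rose was 1. Without PDEF shRNA replicate 1 or 2 limma gave 0, with 8 and 10 at an unadjusted p under 0.05. Of 23 pro-apoptotic genes 3 rose, with 6 adjusted over the list alone. They were FAS, TNFRSF10B and BCL2L11, which encodes the BH3-only protein BIM (2.33-fold). TNFRSF10B and BCL2L11 did not pass as the mean of their probe sets. With any 1 of the 4 arrays left out limma gave 0, with 5 to 9 at an unadjusted p under 0.05. The list's median was 0.13 and its camera adjusted p 0.0015, with adjusted p = 0.146 with an estimated correlation. With fry it did not pass (adjusted p = 0.065). Of 15 anti-apoptotic genes limma called 0, with 6 at an unadjusted p under 0.05, and 2 rose and 1 fell adjusted over the list alone. Its camera adjusted p was 0.105. BCL2 was at 0.88 ± 0.14 (adjusted p = 0.051) and TNFAIP3 at 1.08 ± 0.20 (adjusted p = 0.081).

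Several stress lists were higher. Of 21 NRF2 and oxidative stress genes 3 rose, with 12 adjusted over the list alone and a median of 0.38. They were HMOX1, heme oxygenase 1 (2.60-fold), the cystine transporter gene SLC7A11 (2.57-fold) and TXNRD1 (1.00 ± 0.10), whose other probe set was at −0.01. For the list, camera gave an adjusted p of 3.46e-07, and adjusted p = 0.129 with an estimated correlation. Of 27 unfolded protein response genes 2 rose, with 5 adjusted over the list alone and a median of 0.13. These were the stress-induced transcription factors ATF3 (3.90-fold) and DDIT3 (1.96-fold), while the chaperone genes HSPA5 and HSP90B1, chosen after their values were seen, were at 0.45 and 0.04 and did not pass. The camera adjusted p was 1.46e-05, and adjusted p = 0.129 with an estimated correlation. Of 24 NF-kB and inflammatory genes RELB rose (2.09-fold), with 11 that rose and 1 that fell adjusted over the list alone. The list's median was 0.14 and its camera adjusted p 0.0022, with adjusted p = 0.146 with an estimated correlation. Of 24 hypoxia and glycolysis genes P4HA2 rose (0.67 ± 0.09) and PPP1R3C fell (−0.96 ± 0.12), with 2 and 1 adjusted over the list alone. Neither passed as the mean of its probe sets. Its camera adjusted p was 0.048, with adjusted p = 0.235 with an estimated correlation, and the call ended with another normalization, with either filter on dim genes and without any 1 of the 4 arrays. With an array left out limma called 0 genes of these 4 stress lists, with 3 to 12 per list at an unadjusted p under 0.05, except 1 unfolded protein response gene without control replicate 1.

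**Figure D2:**
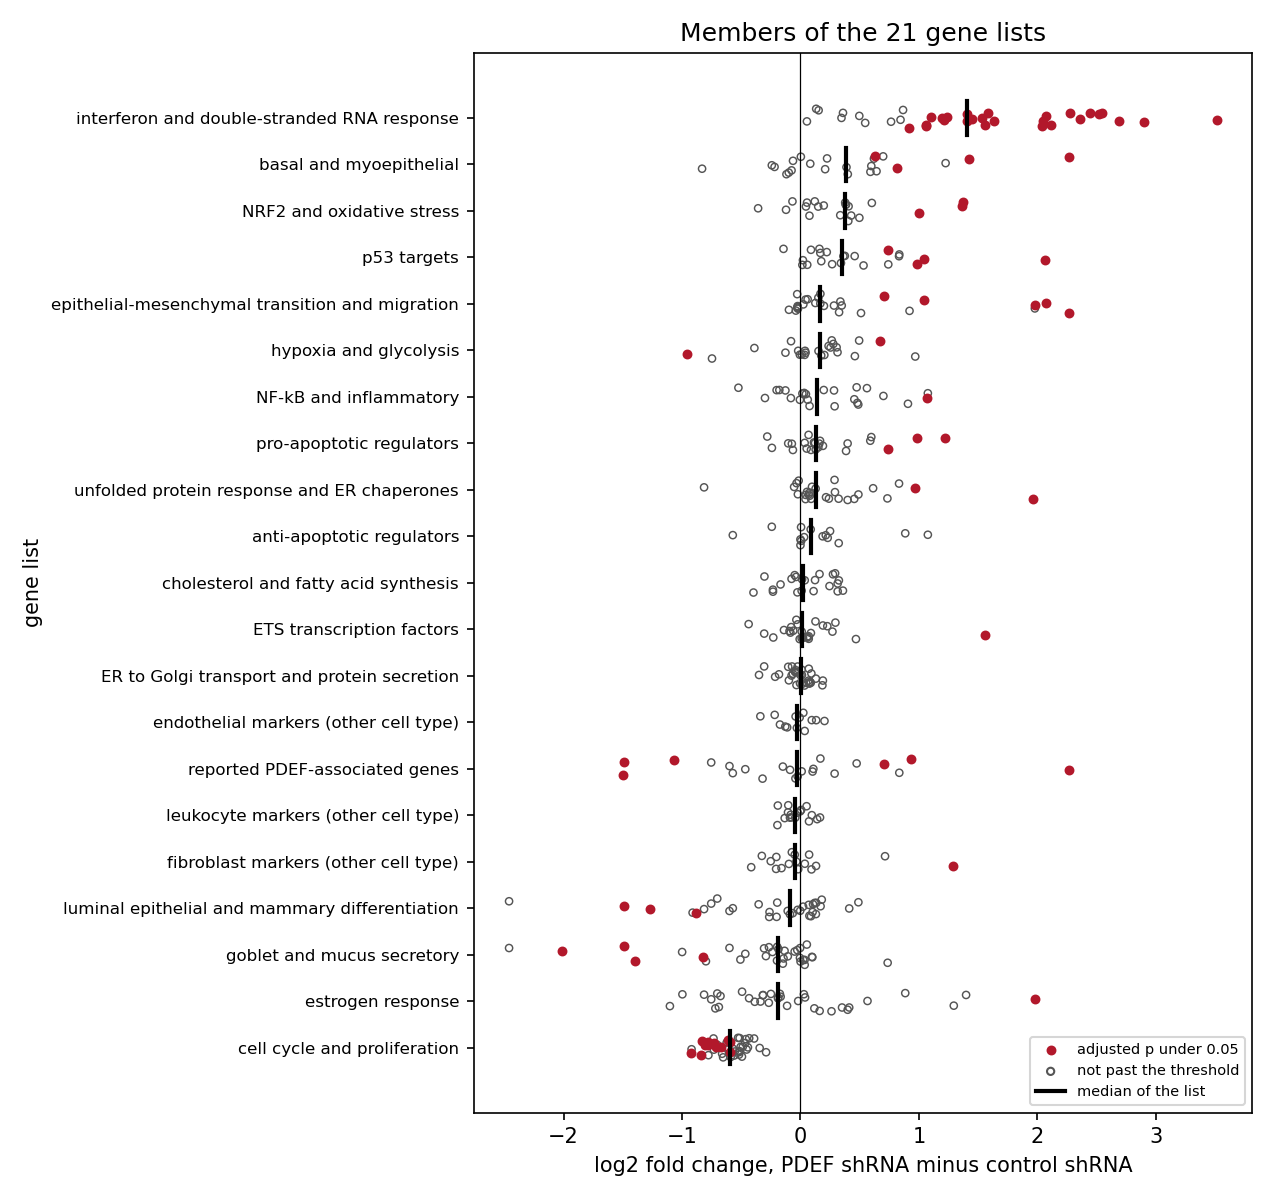
Each row is 1 of the 21 gene lists; each point is a gene, the horizontal axis is its log2 fold change (PDEF shRNA minus control shRNA), filled points are past an adjusted p of 0.05, and bars are list medians. The interferon list has the highest median (1.41) and the cell cycle list the lowest (−0.59).

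Without a block on the replicate number the estrogen response list did not pass the test between the groups, and its genes differed between replicate numbers. Of 35 measured FHL2, a LIM-domain coregulator, rose (3.95-fold), 0 fell, and 2 rose adjusted over the list alone. The list's median was −0.19 and its camera adjusted p 0.446. With the replicate number as a block it passed as lower (camera adjusted p = 0.017), with 4 members that rose and 4 that fell. With the block and an estimated correlation the camera adjusted p was 0.39. PGR, the progesterone receptor gene, was at −1.10 ± 0.73 (adjusted p = 0.640) and TFF1 at −0.75 ± 0.32 (adjusted p = 0.440), both estrogen-induced genes. PGR was 7.99 and 9.42 in control replicates 1 and 2, and 6.62 and 8.58 in PDEF shRNA replicates 1 and 2. GREB1, chosen after its values were seen, was 7.78, 9.79, 7.99 and 9.64 in the same order. Replicate 2 exceeded replicate 1 for 34 of the 35 genes in the controls and for 35 with PDEF shRNA, by medians of 0.90 and 0.81. Within replicate 1 the median of PDEF shRNA minus control was −0.15 and within replicate 2 it was −0.20, with 21 genes lower in each. With 1 array left out, which leaves the replicate numbers unequal between the groups, the direction of the list varied. Its median was 0.10 without control replicate 2 (adjusted p = 0.017) and 0.19 without PDEF shRNA replicate 1 (adjusted p = 0.019). It was −0.55 without control replicate 1 (adjusted p = 0.00015) and −0.57 without PDEF shRNA replicate 2 (adjusted p = 2.6e-05).

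**Figure D3:**
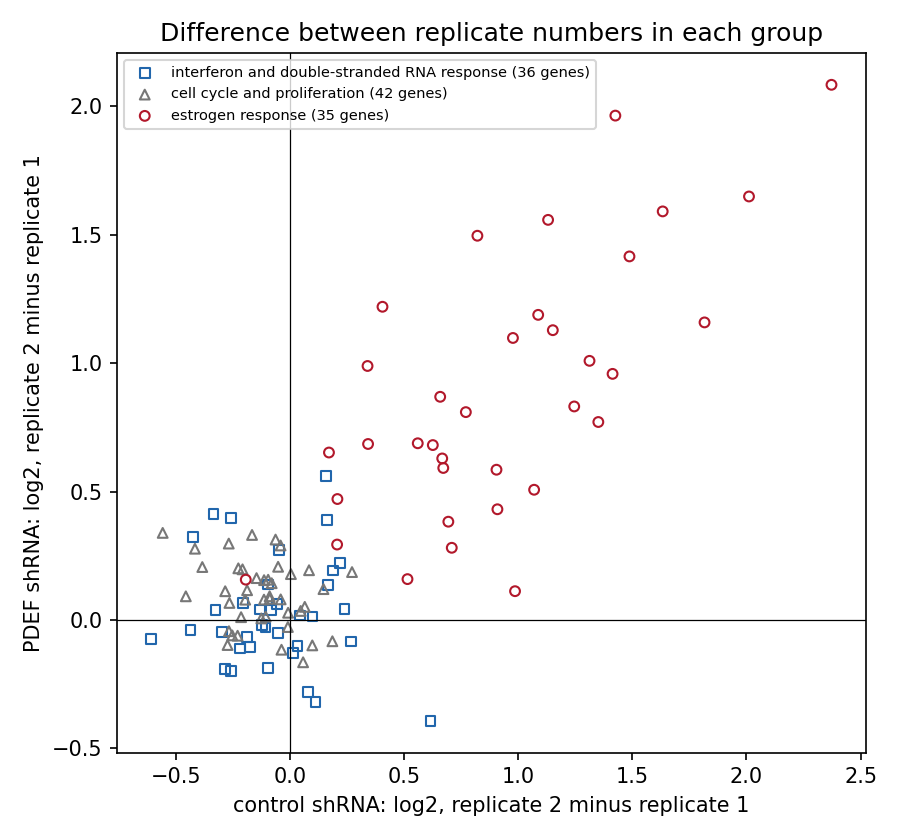
Each point is a gene of the estrogen, cell cycle or interferon list; the axes are the log2 difference of replicate 2 minus replicate 1 in the control arrays (horizontal) and in the PDEF shRNA arrays (vertical). For 34 of 35 estrogen response genes both differences are positive, and the medians of the cell cycle list are −0.11 and 0.09.

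The remaining lists did not pass. Of 26 ETS transcription factors, the family of PDEF, ETS2 rose (2.95-fold), with a list median of 0.02 and a camera adjusted p of 0.446. In 34 ER to Golgi transport genes limma called 0, with 2 at an unadjusted p under 0.05. SEC23A was at −0.35 and MCFD2 at −0.31, and the camera adjusted p was 0.468, with a median of 0.005, a mean of −0.01 and a test direction of lower. Without control replicate 2 this list passed as lower (adjusted p = 0.038). In 22 cholesterol and fatty acid synthesis genes limma called 0, with 5 at an unadjusted p under 0.05. SCD was at −0.40 and SQLE at 0.36, and the camera adjusted p was 0.486. None of the 3 lists of markers of other cell types passed. Of 17 fibroblast markers COL5A1 rose (2.44-fold), with a list median of −0.05, a mean of 0.03, a test direction of lower and an adjusted p of 0.468. In 17 leukocyte markers limma called 0, with 0 at an unadjusted p under 0.05. CORO1A and CD3D were at −0.19 each, and the median was −0.04 (adjusted p = 0.398). In 13 endothelial markers limma called 0, with 1 at an unadjusted p under 0.05. KDR was at −0.34 and TIE1 at −0.22 (camera adjusted p = 0.398). In all, 12 of 21 lists passed with camera, 9 higher and 3 lower. With an estimated correlation camera called 0, with 8 at an unadjusted p under 0.05, in a test on 2 residual degrees of freedom, and fry called 10. FHL2, ETS2 and COL5A1 did not pass with any 1 of the 4 arrays left out.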

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

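These results come from probe sets outside the comparison of named genes, and the test of every probe set was planned. Of 56 array control probe sets without a gene symbol, 3 were higher with PDEF shRNA past the threshold, with log2 fold changes from 1.47 to 1.59, and 0 were lower. Of 13522 other probe sets without a single gene symbol, 32 were higher and 3 lower, with a largest rise of 2.17 and a largest fall of −0.91. They were set apart as signal in data that the named genes do not use.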

How the results depend on the processing

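Outside the fits that left out an array, SPDEF stayed lower and past the threshold in all 10 alternatives. The count of 324 genes (220 rose, 104 fell) stayed within 1.5 times in 10 alternatives. It was 156 (122 and 34) at an absolute log2 fold change of at least 1, and 595 (373 and 222) at an adjusted p under 0.1, which follows from the thresholds. Leaving out 1 array, a fit with fewer samples, gave 0 to 54 genes, with 0 to 48 that rose and 0 to 6 that fell, and an SPDEF log2 fold change of −2.87 to −2.37, past the threshold in none of the 4. Of the values of single named genes, 706 were on the same side outside these fits, 13 gained a call and 13 lost one. No named gene changed direction outside these fits. With an array left out, 200 lost the call and 100 stayed on the same side. The 12 lists past the threshold became 0 with an estimated correlation, a test on 2 residual degrees of freedom. Each fit without 1 array also gave 12, but not the same lists: hypoxia lost its call in all 4 and the luminal list without control replicate 2. Estrogen response passed in all 4, in opposite directions, and ER to Golgi transport without control replicate 2.

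The fibroblast list, which did not pass, took the opposite test direction in 4 alternatives, with a median of 0.635 among the brighter 9888 genes, −0.013 with the mean of a gene's probe sets, −0.00093 with every probe set and −0.048 with fry. With an array left out, list medians ran from −0.084 to −0.0051 for fibroblast markers, −0.57 to 0.19 for estrogen response, −0.082 to 0.054 for ER to Golgi transport and 0.012 to 0.059 for cholesterol synthesis, each changing its test direction in at least 1 fit. The cause was not tested.

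With the replicate number as a block, 405 genes changed (273 rose, 132 fell), 294 of them shared with the fit without it. The deviations of same-numbered arrays correlated at 0.27 over genes and 0.11 over probe sets. The labels do not say that the numbers pair the arrays, and the fit without the block was planned as the main one. That fit counts a difference between replicate numbers as spread, which widens the SE of genes that differ between them. With the block the estrogen list passed as lower (median −0.19, adjusted p = 0.017, and adjusted p = 0.39 with an estimated correlation), with 4 members that rose and 4 that fell. List members that fell became 6 luminal, 6 goblet and 8 cell cycle genes, against 3, 4 and 12 without the block, and those that rose became 2 NF-kB, 2 hypoxia and 1 anti-apoptotic, against 1, 1 and 0. Other list counts stayed within 1.5 times. Dim probe sets, whose log2 values are compressed by RMA, limit what these arrays can show.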

Other observations

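The 6 lists here, the contrast between replicate numbers and the tests on leukocyte markers, hybridisation controls, genes lowered by estrogen and other splits of the arrays were chosen after the results were seen. Genes of MHC class I antigen presentation, which interferon also induces, were higher with PDEF shRNA. Of 18 measured 8 rose and 0 fell, with a median of 0.69, among them the peptide transporter gene TAP1 (2.72-fold) and B2M, the invariant chain (2.12-fold). HLA-B (1.10) and HLA-C (1.12) rose too, but HLA probe sets may detect each other's transcripts. The camera adjusted p was 1.81e-14, and adjusted p = 0.0605 with an estimated correlation. Of 26 ATF4 amino acid response genes 5 rose, with a median of 0.47. ATF3, SLC7A11 and DDIT3 were joined by GDF15 (3.38-fold) and the amino acid transporter subunit SLC3A2 (0.92). The camera adjusted p was 1.13e-09, and adjusted p = 0.0605 with an estimated correlation.

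Of 20 TGF-beta and SMAD target genes 7 rose, with a median of 0.66, including PMEPA1 (2.30-fold) and JUNB (0.68). SNAI2, LOXL2 and TGFB2 in this list were known to be higher when it was written, so the list is not independent evidence. The camera adjusted p was 1.59e-13, and adjusted p = 0.158 with an estimated correlation. Of 10 aryl hydrocarbon receptor targets CYP1A1 (4.03-fold) and UGT1A6 (2.54-fold) rose, while CYP1B1 was at 0.44 and did not pass. The camera adjusted p was 0.0098, and adjusted p = 0.158 with an estimated correlation. Of 17 glutathione S-transferase genes GSTM4 (3.79-fold) and GSTM2 (0.91) rose. These are related genes, and whether their probe sets are separate was not checked. The list did not pass (median −0.06, camera adjusted p = 0.827). Nor did the list of 13 genes that estrogen lowers in MCF7 (adjusted p = 0.843).

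The interferon list was higher with PDEF shRNA by a median of 1.41. Leukocytes in the cultures would raise their own markers, but the upper quartile of the 17 leukocyte markers was 0.052 and the highest, PTPRC, 0.165, while the most abundant, CORO1A, was at 7.95 in controls and 7.75 with PDEF shRNA. Hybridisation controls were lower by 0.175 with PDEF shRNA (−0.175). The quantile step had already evened out array brightness, so this value cannot test for brighter arrays. Of 10000 matched random lists 0 reached the median (range −0.099 to 0.134), against a trend with expression level. A response to this hairpin or vector, rather than to loss of PDEF, cannot be told apart: no array has loss of PDEF without the hairpin, or the reverse. The PDEF shRNA arrays differed by a median of 0.0023 over the list. A role of PDEF in holding these genes down stays an untested hypothesis.

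The cell cycle list was lower by a median of 0.59 (−0.59), and 0 of 10000 matched random lists were as low (range −0.092 to 0.129), against a trend with expression level. Lower estrogen signalling is a candidate explanation, since estrogen drives division of MCF7 cells. Between the groups the estrogen list's median was −0.19, and it did not pass without a block (camera adjusted p = 0.446). With the replicate number as a block it passed as lower (camera adjusted p = 0.017). Between replicate numbers the estrogen list differed by a larger median of 0.79. There the cell cycle list differed by −0.11 in controls and 0.09 with PDEF shRNA, a mean of −0.0042. A larger estrogen difference thus came without a cell cycle shift in 1 direction, but these values meet neither outcome set for the test. Lower estrogen signalling cannot be told apart from other effects of PDEF loss, of the interferon response, or of the hairpin or vector.

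Estrogen response genes were higher in replicate 2 of both groups by a median of 0.79, with 25 genes past the threshold between replicate numbers (23 higher, 2 lower) in a fit that also holds the shRNA group. MYBL1 differed by 2.23 ± 0.12 SE and PGR by 1.69 ± 0.15 (limma, adjusted p = 0.033 and 0.049). Hybridisation controls differed by −0.397 in the controls but by 0.382 with PDEF shRNA, values that cannot test array brightness after the quantile step. Of 10000 matched random lists 0 were as high (range −0.089 to 0.096), which argues against a trend with expression level. More residual estrogen in replicate 2 is a candidate explanation: 10 of 13 genes that estrogen lowers were lower in replicate 2 of both groups, with a median of −0.334 (camera adjusted p = 3.52e-06). The TGF-beta and SMAD list was also lower in replicate 2 (median −0.16, camera adjusted p = 6.79e-07, 12 of 20 genes lower in both groups). The luminal list was higher (median 0.04, camera adjusted p = 0.030), but it shares TFF1, XBP1, STC2 and CA12 with the estrogen list. These camera p-values are at the preset correlation of 0.01 alone and are too small where members are correlated. In the fit between groups the estimated correlation was 0.865 for the estrogen list, 0.428 for genes lowered by estrogen and 0.392 for the TGF-beta list. That fit leaves the difference between replicate numbers in its residuals. These correlations therefore restate that difference in part and are no separate measure of it. The difference between replicate numbers may not be limited to estrogen genes, and other causes stay open.

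The 4 arrays can be split into 2 and 2 in 3 ways, so no share under 0.05 can be reached. The real split (1 of the 3) gave 324 genes and the highest of the others 0, with 2441 against 788 (the split by replicate number) and 470 genes at an unadjusted p under 0.05 with limma. These fits hold the split alone. The 25 genes between replicate numbers come from a fit that also holds the shRNA group, so the 0 does not show that replicate numbers have no effect.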
